A study of Mus musculus with 12 samples.

How the data were processed

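Small RNA libraries were made from exosomes of primary mouse hepatocytes, which per the labels were kept in Williams' E medium with fetal bovine serum, in 3 groups (lean, 4 weeks of HFD and 16 weeks of HFD) of 4 libraries each. The deposited table gives 1 value per miRNA and library in CPM, which the authors computed from the miRNA reads of each library. Per the submitters' processing notes, cutadapt 1.13 and edgeR 3.16.5 were used with the mm10 build. The aligner, the miRNA annotation and the treatment of reads with several matches are not stated, and the name of the deposited table calls its miRNAs unique mouse ones, without saying what that excludes.

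The values were checked before use. In each column, 1 step (the CPM of 1 read) was found of which the values are whole multiples, and the depth of the library follows from it. Of 2664 values above 0, 2617 (98.2%) were whole reads within a relative tolerance of 1e-06. The exceptions lie in 7 miRNAs in the lean and 16-week columns, besides 1 value of miR-486a-5p in 4-week replicate 3 (65.3 CPM, 0.292 reads). As deposited, 0 of the 8 lean and 16-week columns sum to 1000000 CPM, and 5 do after the same-numbered lean and 16-week values of the 7 miRNAs are exchanged. Of the other 3, lean replicate 2 lacks 2 reads, 16-week replicate 2 lacks 2000 CPM and 16-week replicate 3 lacks 4000 CPM. The deposited values were used unchanged in the comparisons, the 7 miRNAs are marked in the text, and results without them or with the values exchanged back were computed as alternatives. Precision follows the depth. A single read equals 32.9 to 72.7 CPM in lean, 223 to 425 CPM at 4 weeks and 26.6 to 48.7 CPM at 16 weeks. Folds against a group at 0 in all libraries use a floor of 3 reads over the group, and no fold is read where the other group is at or under that floor. Differences of log2(CPM + 1) over such groups are set by the pseudocount and are marked where listed.

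The groups, comparisons, tests, miRNA lists, naming rule and most alternatives were chosen before the data were examined. Each pair of groups was compared with limma 3.58.1 (R 4.3.3) on log2(CPM + 1), with empirical Bayes and a mean-variance trend, for miRNAs of at least 10 CPM in at least 4 of 12 libraries. All 12 libraries entered 1 fit. Calls need a Benjamini-Hochberg adjusted p under 0.05, with tests of either direction. Of 19 fixed miRNA lists, those with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists cover hepatocyte-enriched miRNAs, lipid and insulin metabolism, the let-7, miR-30, miR-29, miR-15/16, miR-181 and miR-34 families, the miR-17-92 and miR-23-27-24 clusters, the Dlk1-Dio3 and Sfmbt2 clusters, and markers of leukocytes, endothelium, stellate cells and fibroblasts, cholangiocytes, red blood cells, muscle and neural cells. Whole profiles were compared by the mean Euclidean distance between minus within groups, with an exact permutation test over 70 assignments, and shares of the CPM by exact permutation tests with Benjamini-Hochberg adjustment over the comparisons. The count test was edgeR 4.0.16 (quasi-likelihood, after its own filter and scaling) on the recovered reads, with the 7 miRNAs left out. DESeq2 1.42.0 was run on the same reads as an alternative added after the data were seen.

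The tests were tried on simulated data at the real depths. The reads were drawn from the kind of count model that edgeR fits, with 1 dispersion (0.162) for all miRNAs, which favours edgeR. With no change between groups, limma on log2(CPM + 1) called up to 29 miRNAs lower at 4 weeks than in lean and up to 44 higher at 16 than at 4 weeks in 20 draws, while edgeR called 0. With planted 8-fold changes and CPM from the simulated column totals, it found 18.9% of the changed miRNAs that it tested at 4 weeks against lean, 47.5% at 16 weeks against lean and 48.4% at 16 against 4 weeks, while edgeR found 5 of 5, 15 of 15 and 14 of 14 that it tested. At 2-fold limma found 5.71%, 2.70% and 12.9%, and edgeR 3 of 6, 5 of 10 and 1 of 8. False calls in these draws numbered 12, 2 and 35 with limma (of 215, 208 and 193 unchanged miRNAs tested), and 0, 1 and 1 with edgeR. In the set for 16 against 4 weeks the most abundant miRNA was also changed, by 3 on the log2 scale. The planned test was kept, its counts are printed beside those of the simulation, and the miRNAs called by both tests lead the text. That choice was made after the values were seen.

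The rule for naming miRNAs took, per comparison, the 10 with the largest fold change in each direction past the threshold, or all that pass and then those with the smallest p up to 8 where fewer than 8 pass. To these were added up to 4 members of each tested list with the highest mean CPM and up to 4 called members, the 5 most abundant miRNAs, and miR-3075, miR-122, miR-690, miR-223 and miR-155. Members of tested lists that were not called are in part given only by the counts of their list. Others called by both tests or abundant in liver were named after their values were seen. Hairpin positions and host genes come from the GENCODE annotation of mm10, matched by miRNA name for 575 of the 618 detected names. Alternatives were pseudocounts of 0.5 and 5, filters from none to 100 CPM, median-of-ratios and quantile scaling, CPM without the 5 most abundant miRNAs, other variance models, fits of 2 groups, the replicate number as a block, edgeR, and leaving out each library. Added after the data were seen were the 7 miRNAs left out or exchanged back, a mean of at least 1000 CPM, DESeq2, and thinning to 2335 reads per library. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sample was left out.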

Results

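Small RNA was sequenced from exosomes, the small vesicles that cells release, collected from the culture medium of primary mouse hepatocytes. The hepatocytes came from lean mice on normal chow, from mice fed a high-fat diet (HFD) for 4 weeks and from mice fed it for 16 weeks, with 4 libraries in each of the 3 groups. The labels do not say whether the libraries of a group came from separate mice, so each p-value below measures the spread between these samples. The deposited table lists 1965 mature mouse miRNA names in CPM, reads per library scaled to a common total of miRNA reads, of which 618 were above 0 in at least 1 library and 58 in all 12. The depth was low and differed between groups. The lean libraries held 13748 to 30430 reads of the listed miRNAs, the 4-week libraries 2352 to 4477 and the 16-week libraries 20538 to 37596. A miRNA with no read in any library of a group could stand at up to 36.2 CPM in the lean group, 213 CPM at 4 weeks and 27.1 CPM at 16 weeks (3 reads over the group). Such floors cover counting error of that group only. Folds given below as at least a value use the floor and take the mean of the other group as exact. The number of miRNAs detected per library was 248 ± 32.0 in lean, 158 ± 23.7 at 4 weeks and 260 ± 15.5 at 16 weeks (SD, n = 4 each).

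**Figure D1:**
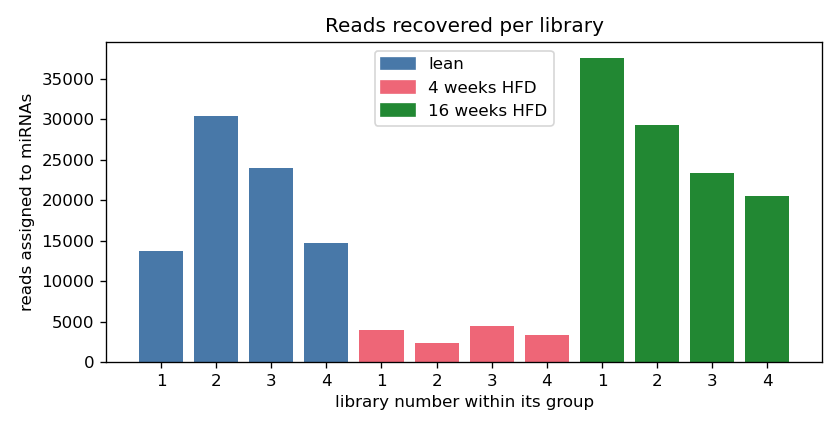
Shown are the miRNA reads of each library, recovered from the deposited CPM, by group. The 4-week libraries lie between 2352 and 4477 reads, below all lean and 16-week libraries.

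In the lean and 16-week columns, the values of 7 miRNAs were not whole reads of their own library: miR-155-5p, miR-299a-3p, miR-300-3p, miR-346-5p, miR-376b-3p, miR-434-3p and miR-486a-5p. Of their 46 values above 0 in these columns, 0 were whole reads as deposited, and 44 became whole reads when the lean and 16-week values with the same replicate number were exchanged (relative tolerance 1e-06). In 186 other miRNAs, all 1284 values were whole as deposited and 0 after the same exchange. The deposited values were kept in the limma comparisons unless an exchange or omission is stated, the count test left the 7 miRNAs out, and each of them is marked where it appears.

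The deposited CPM were dominated by a few miRNAs. They cover the listed miRNAs only, and what was left out is not stated, so the shares below may not hold for all exosome miRNAs. Of the listed miRNAs, miR-101b-3p alone held 62.3% ± 6.53 of the CPM in lean and 60.1% ± 6.52 at 16 weeks, but 25.2% ± 9.01 at 4 weeks (SD, n = 4 each). Its hairpin lies on chromosome 19, 29135279 to 29135375 of the mm10 build, in an intron of Rcl1. The miRNAs that followed by mean CPM were miR-5099 (chromosome 12, 36816205 to 36816278, in no host gene on its strand) and miR-5121 (chromosome 7, 45126918 to 45126991, overlapping an exon of Rpl13a). The 10 most abundant miRNAs together took 80.3% ± 2.07 in lean, 72.2% ± 5.46 at 4 weeks and 82.3% ± 1.45 at 16 weeks. The 4-week share was lower than in lean (exact permutation test, 2-sided, adjusted p = 0.0429; below all lean libraries in 4 of 4; adjusted p = 0.0857 without any one of the lean libraries) and lower than at 16 weeks (adjusted p = 0.0429). The difference between 16 weeks and lean missed the threshold (exact permutation test, adjusted p = 0.171).

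The hepatocyte miRNA miR-122-5p, the most abundant miRNA in liver tissue, had 3 reads in these 12 libraries (1 in lean, 0 at 4 weeks and 2 at 16 weeks), too few for a comparison of its share (exact permutation test, adjusted p = 1 in each comparison). Of 28 miRNA names chosen after the values were seen because they are abundant in liver or blood, 24 had a mean under 100 CPM, among them let-7a-5p, let-7b-5p, miR-148a-3p and miR-22-3p. The exceptions were miR-21a-5p (6074 CPM), miR-192-5p (642 CPM), miR-30d-5p (236 CPM) and let-7c-5p (182 CPM). Markers of other cell types were uneven. No member of the endothelial or muscle lists passed the filter, and the leukocyte miRNA miR-223-3p had 0 reads. The leukocyte-linked miR-146a-5p and miR-511-3p, by contrast, were among the 10 most abundant miRNAs (means of 18970 and 13246 CPM), and miR-125b-2-3p of the stellate and fibroblast list stood at 4355 ± 1097 CPM in lean, 3878 ± 548 at 4 weeks and 6385 ± 1402 at 16 weeks. Also at 0 in all libraries were miR-690 and the other arm of the miR-3075 hairpin.

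The first comparison asked what 4 weeks of HFD did to the miRNA content of hepatocyte exosomes. Among the miRNAs that rose was miR-3075-5p, from 132 ± 34.6 CPM in lean to 2389 ± 1259 at 4 weeks (SD, n = 4 each; log2 fold change 4.08, SE 0.87, adjusted p = 0.00469). All 4 HFD libraries lay above all lean ones. Its hairpin lies in an intron of Zmiz1 (chromosome 14, 25534439 to 25534523), and 0 of 17 alternative settings ended the call. Thinning to 2335 reads per library, which was not among the 17 and also lowers the lean depth, kept the call in 35% of 20 draws. Abundant miR-5099 rose from 37480 ± 16784 to 168083 ± 57641 CPM (log2 fold change 2.24, adjusted p = 0.000647; adjusted p = 0.17 with quantile normalization), and miR-1843b-3p, encoded in an intron of Cop1, from 2933 ± 1252 to 26007 ± 6065 CPM (3.22, adjusted p = 0.000392). In contrast, miR-101b-3p fell by 1.36 on the log2 scale (limma adjusted p = 0.000647). So did miR-802-3p, 1 arm of the hairpin of the obesity-linked hepatic miR-802, by 1.94 (4951 ± 1694 to 1425 ± 691 CPM, limma adjusted p = 0.017).

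Of 267 miRNAs tested with limma, 25 were higher and 31 lower at 4 weeks at an adjusted p under 0.05, and 93 had an unadjusted p under 0.05. The depth gap alone produced calls in one direction. In 20 simulated sets with no change at the real depths, this test called a mean of 12.7 miRNAs lower (at most 29) and 0 higher, of a mean of 325 tested. The 31 lower calls are therefore not read as changes of 31 miRNAs. Of these, 21 were at 0 in all 4-week libraries, 18 of them with a lean level below the 4-week floor, where a difference was not detectable at this depth. A count test on the recovered reads (edgeR, 72 miRNAs tested, the 7 miRNAs with exchanged values left out) called 18 higher and 22 lower, and made 0 calls in the simulated sets. Both tests called 17 miRNAs higher and 7 lower, in the same direction. The choice to lead with these was made after the values were seen.

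Among the 17 higher in both tests, miR-322-3p (log2 fold change 2.13), miR-503-5p (2.10) and miR-351-5p (2.06) come from hairpins within one stretch of chromosome X (53053255 to 53054349). The most abundant of them, miR-351-5p, went from 13021 ± 10549 to 48982 ± 26580 CPM. With CPM recomputed without miR-101b-3p the folds of miR-322-3p, miR-503-5p and miR-351-5p were 1.12, 1.10 and 1.06. The calls for miR-503-5p and miR-351-5p were then lost (limma adjusted p = 0.169 and 0.07). Also higher were miR-501-3p (2.22), encoded in an intron of Clcn5, and miR-362-5p (2.59). The miRNA miR-146a-5p, an NF-κB-induced regulator of inflammatory signalling, rose from 4221 ± 3243 to 19647 ± 7486 CPM (2.40, adjusted p = 0.00297). Abundant miR-5121 rose by 2.75, with 3 of 4 HFD libraries above all lean ones. The others were miR-1927 (6.48), miR-182-5p (4.86), miR-6931-5p (4.05), miR-544-5p (3.48), miR-7242-3p (2.26), miR-24-2-5p (2.02) and miR-455-3p (1.95). The recomputation without miR-101b-3p also ended the limma calls for miR-182-5p, miR-362-5p, miR-7242-3p, miR-24-2-5p and miR-455-3p, while the rest of the 17 kept theirs. The folds of limma rest in part on libraries at 0, and those of edgeR were smaller for all 17 (1.41 to 5.14), among them 5.14 for miR-1927 and 2.59 for miR-182-5p. Leaving out lean replicate 2 moved miR-1927 to 4.87 and lean replicate 4 moved it to 7.43, and for miR-182-5p the range was 2.92 (lean replicate 1) to 6.01 (lean replicate 4). The limma call for miR-182-5p was kept only on leaving out lean replicate 2, lean replicate 4 or 16-week replicate 1, and lost without any of the other 9 libraries (adjusted p = 0.0553 to 0.0856) and in 6 of 18 other settings. The miRNA miR-200a-3p, an epithelial miRNA at 0 in all lean libraries, stood at 451 ± 312 CPM at 4 weeks, at least 12.4-fold higher than the lean floor (limma adjusted p = 0.00282). It was too sparse for the count test. So were 4 others among the 10 largest increases in limma: miR-6237 (at 0 in lean and 522 ± 545 CPM at 4 weeks, at least 14.4-fold above the lean floor), miR-677-5p (4.85), miR-501-5p (4.44) and miR-7672-5p (4.43). These calls were lost on leaving out 1 library: any lean one for miR-6237 (limma adjusted p = 0.0594 to 0.0785), lean replicate 2 or 4 or 4-week replicate 2 or 3 for miR-677-5p (0.0601 to 0.0789), lean replicate 1 or 4-week replicate 2 or 3 for miR-501-5p (0.0599 to 0.0636), and any but lean replicate 4 and 4-week replicate 3 for miR-7672-5p (0.0575 to 0.109). The abundant miR-151-3p, encoded in an intron of Ptk2, was called by limma (1.20) but not by the count test (0.71, adjusted p = 0.0596).

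The 7 lower in both tests included miR-3068-5p, which fell by 1.60, miR-1843a-5p, which fell by 1.65, and miR-872-5p, which fell by 1.85 on the log2 scale. Also lower, miR-674-3p fell by 2.49 (10526 ± 1987 to 2958 ± 2610 CPM), and miR-6921-3p, at 206 ± 283 CPM and thus near the floor at 4 weeks, fell by 3.57 in edgeR and fell by 6.27 in limma, the latter resting on 4-week libraries at 0. Leaving out lean replicate 2 ended the limma call for miR-802-3p (adjusted p = 0.055), as did a fit of the 2 groups alone (adjusted p = 0.059), and without limma's variance trend those for miR-101b-3p, miR-802-3p and miR-351-5p were lost (adjusted p = 0.0979, 0.0661 and 0.0661). The 10 largest decreases in limma were those of miR-376b-5p, miR-15a-3p, miR-6964-3p, miR-7032-3p, miR-543-5p, miR-1945, miR-1982-3p, miR-341-3p, miR-219c-5p and miR-6971-3p, and all except miR-1982-3p were at 0 at 4 weeks. Against the 4-week floor miR-376b-5p was at least 2.68-fold lower, miR-15a-3p and miR-6964-3p lay just above it in lean (247 and 241 CPM), and the other 6 had a lean level under it. The call for miR-1982-3p (894 ± 854 to 55.8 ± 112 CPM) was lost without any of 6 libraries (lean replicates 1, 2 and 3 and 4-week replicates 1, 2 and 4; limma adjusted p = 0.0536 to 0.0832). Over the scalings run as alternatives, the median shift of all miRNAs ranged from -0.60 (CPM without the 5 most abundant) to 1.23 (quantile normalization). The recomputation without miR-101b-3p, which is not among these scalings, moved the median further down than -0.60. With it, limma called 13 miRNAs higher and 50 lower at 4 weeks, against 25 and 31 with the deposited CPM. Fold changes and the numbers of calls in each direction are thus relative to the scaling.

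**Figure D2:**
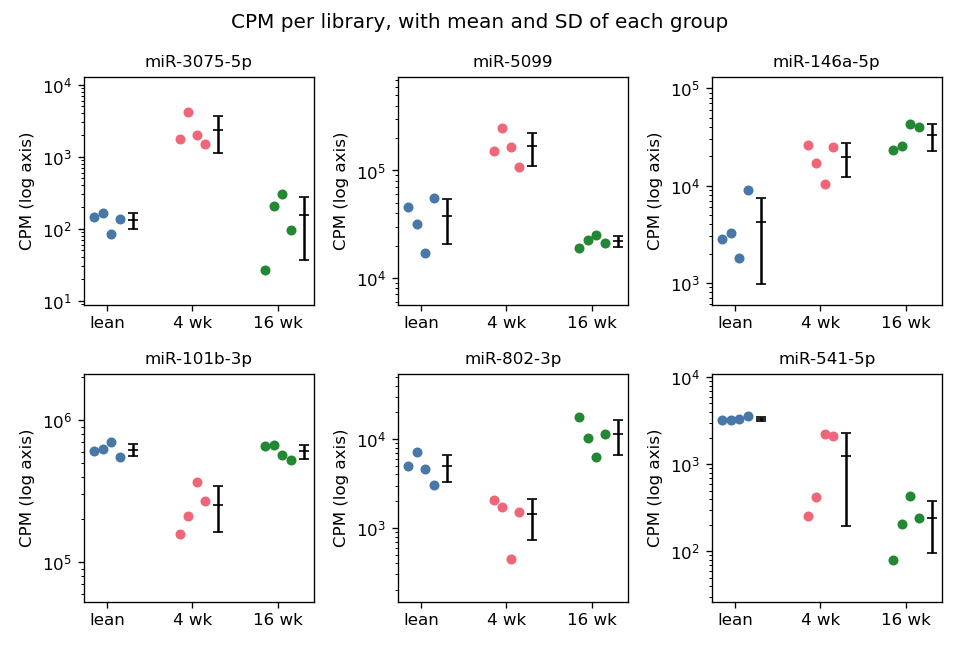
Points show the CPM of 6 miRNAs in each library on log axes, with the mean and SD of each group (n = 4). The highest group mean of miR-3075-5p and miR-5099 was that at 4 weeks (2389 and 168083 CPM), that of miR-146a-5p was at 16 weeks (33042 CPM), and the lowest of miR-541-5p was at 16 weeks (239 CPM).

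Of 19 fixed miRNA lists, 9 had at least 3 tested members, and limma's camera called 0 of them at 4 weeks. The Dlk1-Dio3 cluster, a large imprinted miRNA cluster on chromosome 12, was the nearest (unadjusted p = 0.0136, adjusted p = 0.123; adjusted p = 0.52 with an estimated correlation). Of its 19 tested members, 2 were called higher and 5 lower, or 2 higher and 9 lower adjusted over the list alone. One of the higher ones, miR-376b-3p, is among the miRNAs with exchanged values, and the other was miR-544-5p. All 5 lower ones were at 0 in all 4-week libraries, and the lean levels of 4 of them lay under the 4-week floor, where a difference was not detectable. With the values exchanged back, miR-376b-3p was no longer called and miR-300-3p was called lower (-7.03, limma adjusted p = 0.0111; -2.14 and 0.393 as deposited). With the 7 miRNAs left out or exchanged back camera called the list in limma at the preset correlation of 0.01 (adjusted p = 0.0155 and 0.00248), a call that rests in part on such members. An estimated correlation was not run for these 2 settings. Among the hepatocyte-enriched miRNAs, 0 rose and 2 fell of 5 tested (1 and 2 adjusted over the list alone; limma camera adjusted p = 0.989). The 2 were miR-101b-3p and miR-802-3p, while miR-192-5p stood at 238 ± 120 CPM in lean and 571 ± 222 at 4 weeks without passing the test. The other arm of the miR-101b hairpin, miR-101b-5p, went up (46.1 ± 37.4 to 376 ± 173 CPM, log2 fold change 4.05). It missed the threshold as well (limma adjusted p = 0.0645). Of the 6 tested miR-15/16 members, miR-322-3p rose and miR-15a-3p and miR-16-1-3p were called lower (1 and 3 adjusted over the list alone; limma camera adjusted p = 0.989), both at 0 at 4 weeks. For miR-16-1-3p that call was lost without any of 6 libraries (lean and 4-week replicates 1, 2 and 3; limma adjusted p = 0.0532 to 0.115). Among 6 leukocyte-linked miRNAs, miR-146a-5p alone was called (1 and 0 adjusted over the list alone; limma camera adjusted p = 0.989), and with the exchanged values put back miR-155-5p was called higher as well (5.23, limma adjusted p = 0.035; 1.03 and 0.698 as deposited). In both the miR-15/16 and the leukocyte list the median log2 fold change was negative (-1.49 and -0.61) and so was the mean (-2.09 and -0.69), while camera gave the direction as up. Of 4 lipid and insulin metabolism miRNAs, miR-182-5p was higher and miR-802-3p lower (1 and 2 adjusted over the list alone; limma camera adjusted p = 0.989). In the stellate and fibroblast list, 1 of 4, miR-99a-3p, was called lower by limma (1 adjusted over the list alone), at 64.1 ± 128 CPM and below the floor at 4 weeks, a call kept only on leaving out 4-week replicate 1. The let-7, miR-30 and miR-17-92 lists had no called member, and adjusted over the list alone 1 miRNA of the miR-30 list was lower and 0 in the others. Camera gave these 3 lists and the stellate and fibroblast list an adjusted p of 0.989 in limma. In the lists with fewer than 3 tested members, which camera did not test, the members measured were miR-24-2-5p, miR-181a-2-3p, miR-219a-1-3p, miR-200a-3p, miR-429-3p and miR-486a-5p, the last with exchanged values. No member of the miR-29, miR-34 or Sfmbt2 lists passed the filter.

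The profiles of lean and 4-week exosomes were further apart between groups than within them by a mean Euclidean distance of 14.2 on the log2 scale (one-sided exact permutation p = 0.0286, the smallest that 70 assignments allow). Depth also differs between these groups, and miRNAs at 0 add to the distance, so it does not tell depth and HFD apart.

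The second comparison asked what differed after 16 weeks of HFD. The inflammation-linked miR-146a-5p rose from 4221 ± 3243 CPM in lean to 33042 ± 10271 at 16 weeks (SD, n = 4 each; log2 fold change 3.19, SE 0.47, adjusted p = 0.00138; edgeR 3.05, adjusted p = 5.5e-06), with all 4 HFD libraries above all lean ones. In the other direction, miR-541-5p of the Dlk1-Dio3 cluster fell by 4.03 (SE 0.80, adjusted p = 0.00815), from 3334 ± 191 to 239 ± 144 CPM. Its hairpin lies in an intron of the noncoding gene Mirg (chromosome 12, 109742409 to 109742498). In the same cluster, miR-329-5p, miR-376c-3p and miR-543-5p, present in all 4 lean libraries, had no read at 16 weeks. Against the 16-week floor they were at least 5.99-fold, 2.60-fold and 6.50-fold lower (limma adjusted p = 0.00179, 0.00196 and 0.00138), though the call for miR-376c-3p was lost with no filter on low values (adjusted p = 0.102). These folds take the lean means (162 ± 138, 70.3 ± 23.3 and 176 ± 70.5 CPM) as exact. With the error of those means the folds could be smaller. At 16 weeks miR-3075-5p stood at 157 ± 120 CPM, without passing the test against lean (adjusted p = 0.966).

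With limma, 3 miRNAs were called higher and 4 lower of 267 tested, and 50 had an unadjusted p under 0.05. Simulated sets with no change gave a mean of 0.65 higher (at most 2) and 0.15 lower (at most 1). The higher ones were miR-146a-5p, miR-24-2-5p (4502 ± 3068 to 13992 ± 2557 CPM; 1.85, limma adjusted p = 0.0362) and miR-376b-3p, whose lean and 16-week values are among those exchanged and whose direction turned when they were exchanged back (log2 fold change -7.50). The call for miR-24-2-5p was lost on leaving out any of 8 libraries (lean replicates 1, 2 and 3, 4-week replicate 3 and each 16-week library; limma adjusted p = 0.0512 to 0.186), and without limma's variance trend (adjusted p = 0.168). Next among the lower ones by p, miR-3103-3p, miR-341-3p and miR-679-5p missed the threshold (limma adjusted p = 0.057 each). The count test called more, 13 higher and 12 lower of 72, and 3 miRNAs were called by both: miR-146a-5p, miR-24-2-5p and miR-541-5p. Those called by the count test alone included miR-802-3p (11493 ± 4832 CPM; log2 fold change 1.24, adjusted p = 0.023), miR-192-5p (1118 ± 633 CPM; 2.26, adjusted p = 0.0028), and miR-503-5p (1641 ± 498 CPM; 2.02, adjusted p = 0.0028). The miRNA miR-511-3p, encoded in an intron of the macrophage mannose receptor gene Mrc1 (chromosome 2, 14261003 to 14261081), was also among them (9740 ± 7709 in lean and 21216 ± 4566 CPM; 1.23, adjusted p = 0.023; limma adjusted p = 0.157). The other arm of this hairpin, miR-511-5p, did not rise with it (1814 ± 1004 in lean and 1122 ± 546 CPM at 16 weeks). Its log2 fold change was -0.59 (limma adjusted p = 0.826). Between 16 weeks and lean, miR-101b-3p differed by less than the spread between replicates (log2 fold change -0.04, SE 0.20), with a positive sign without lean replicate 3 (0.02) or 16-week replicate 4 (0.03). Scalings moved the median of all miRNAs by -0.32 (median-of-ratios) to 0.15 (quantile normalization).

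Of the lists, camera called 1, the Dlk1-Dio3 cluster, as lower (limma adjusted p = 0.000671), a call that was lost in limma at an adjusted p = 0.0584 with an estimated correlation. With the 7 miRNAs left out or exchanged back it was kept (limma camera adjusted p = 4.5e-11 and 6.1e-14). Of 19 tested members 1 was higher and 4 lower, or 4 higher and 11 lower adjusted over the list alone. The 4 higher are miR-299a-3p, miR-300-3p, miR-376b-3p and miR-434-3p, all of them among the miRNAs with exchanged values. Of the other 15 members, 14 had a negative log2 fold change. The call also ended on leaving out any of the 4 lean libraries (limma adjusted p = 0.0663 to 0.434), since members seen only in the 4 lean libraries then failed the filter. The 5 hepatocyte-enriched miRNAs had 0 calls, with miR-192-5p higher adjusted over the list alone (1 and 0; limma camera adjusted p = 0.237). Of 6 miR-15/16 members 0 were called (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.0737). Of 6 leukocyte-linked miRNAs, miR-146a-5p was higher (2 and 1 adjusted over the list alone; limma camera adjusted p = 0.543), the 1 lower being miR-155-5p, whose values are among those exchanged. The median (-0.42) and mean (-0.17) of this list were negative and its camera direction up. The miR-17-92 list had 0 calls, and 1 and 0 adjusted over the list alone, with a median of -0.02 and a mean of 0.73 (limma camera adjusted p = 0.587, up). The lipid and insulin, let-7, miR-30, and stellate and fibroblast lists had 0 calls by either adjustment (limma camera adjusted p = 0.543, 0.587, 0.543 and 0.263). The profile distance was 8.24 (one-sided exact permutation p = 0.0286), and leaving out any of the 16-week libraries gave an exact p of 0.0571.

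The third comparison asked what differed between 16 and 4 weeks of HFD. Several miRNAs higher at 4 weeks than in lean were lower at 16 than at 4 weeks. Both comparisons use the same 4-week libraries, so a deviation of these libraries alone would give both results. With limma, miR-3075-5p fell by 4.27 on the log2 scale (SE 0.87, adjusted p = 0.0063), miR-1843b-3p by 4.09 (SE 0.40, adjusted p = 2.2e-05) and miR-5099 by 2.88 (SE 0.33, adjusted p = 7.6e-05), each with all 4 of the 16-week libraries below all 4-week ones. In the other direction miR-802-3p rose by 3.12 (1425 ± 691 to 11493 ± 4832 CPM, SD, n = 4 each, adjusted p = 0.00203) and miR-101b-3p by 1.32 (adjusted p = 0.00099; the call was lost with quantile normalization and without limma's variance trend). The level of miR-146a-5p was 19647 ± 7486 at 4 weeks and 33042 ± 10271 CPM at 16 weeks (limma log2 fold change 0.79, adjusted p = 0.284; edgeR 1.21, adjusted p = 0.0177).

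With limma, 17 were called higher and 11 lower of 267, with 79 at an unadjusted p under 0.05. In simulated sets with no change at the real depths it called a mean of 21.7 higher (at most 44) and 0.05 lower (at most 1) of a mean of 325 tested, so their number is not read as that of changed miRNAs. Of these, 10 were at 0 in all 4-week libraries, among them miR-15a-3p, miR-16-1-3p, miR-16-2-3p, miR-201-5p, miR-3058-5p, miR-6964-3p and miR-1960. The count test called 15 higher and 15 lower of 72, and both tests called 5 higher and 9 lower. Besides those above, the higher ones were miR-872-5p (1.65), miR-1843a-5p (1.35) and miR-3068-5p (1.15), with edgeR folds of 1.76 to 3.62 for the 5. The lower ones were also miR-6931-5p, which fell by 3.88, miR-7242-3p, which fell by 2.84, miR-1843a-3p, which fell by 2.53, miR-501-3p, which fell by 1.60, miR-151-3p, which fell by 1.28, and miR-6538, which fell by 5.89 in limma and by 3.97 in edgeR (2674 ± 871 to 118 ± 90.8 CPM). For all 9 the fall was smaller in edgeR than in limma. Without 16-week replicate 1 limma gave -4.07 for miR-6538, -2.89 for miR-6931-5p and -3.58 for miR-3075-5p. The limma call for miR-501-3p was lost without 4-week replicate 1 (adjusted p = 0.0587) or 16-week replicate 1 (adjusted p = 0.0807). Quantile normalization, which moved the median of all miRNAs by -1.20 (the other scalings by 0.18 to 0.60), ended the calls for miR-151-3p, miR-501-3p and miR-1843a-3p, as did limma without its variance trend. Median-of-ratios scaling also ended that for miR-1843a-3p, and a fit of the 2 groups alone those for miR-501-3p and miR-6538 (limma adjusted p = 0.0651 each). The macrophage-linked miR-511-3p stood higher at 16 weeks in all 4 libraries (log2 fold change 1.39, limma adjusted p = 0.0937; edgeR 1.75, adjusted p = 0.0021).

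Camera in limma called 0 of the 9 lists in this comparison, and the lowest unadjusted p was 0.0599, for the hepatocyte-enriched miRNAs (adjusted p = 0.4). Of these 5 miRNAs, miR-802-3p and miR-101b-3p rose and 0 fell (2 and 0 adjusted over the list alone). Of 6 miR-15/16 members 3 were called higher, all at 0 at 4 weeks (3 and 1 adjusted over the list alone; limma camera adjusted p = 0.4), where the depth gap gives such calls. In the Dlk1-Dio3 list 2 were called higher (2 and 0 adjusted over the list alone), miR-299a-3p and miR-300-3p, whose 16-week values are among those exchanged. With the values exchanged back both calls were lost (log2 fold change 4.60 and 2.14, limma adjusted p = 0.0918 and 0.471). Without 16-week replicate 1 the call for miR-300-3p was lost (limma adjusted p = 0.0743). The median of this list was 0.00, its mean 0.65 and its camera direction down (limma adjusted p = 0.517). Of the lipid and insulin list miR-802-3p rose (1 and 0 adjusted over the list alone), and of the miR-17-92 list miR-106a-5p was called higher, at 0 at 4 weeks (1 and 0 adjusted over the list alone). The stellate and fibroblast list had 1 higher, miR-99a-3p (1 and 0 adjusted over the list alone), a call lost without any of 6 libraries. Camera in limma gave these 3 lists an adjusted p of 0.517. Of the leukocyte-linked miRNAs 0 were called (0 and 1 adjusted over the list alone, the latter miR-155-5p with exchanged values; limma camera adjusted p = 0.754). The let-7 and miR-30 lists had 0 calls by either adjustment (limma camera adjusted p = 0.929 and 0.517). The profile distance was 11.8 (one-sided exact permutation p = 0.0286), and without any of the 16-week libraries the exact p was 0.0571 to 0.114. Here too the distance does not tell depth and the weeks of HFD apart.

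**Figure D3:**
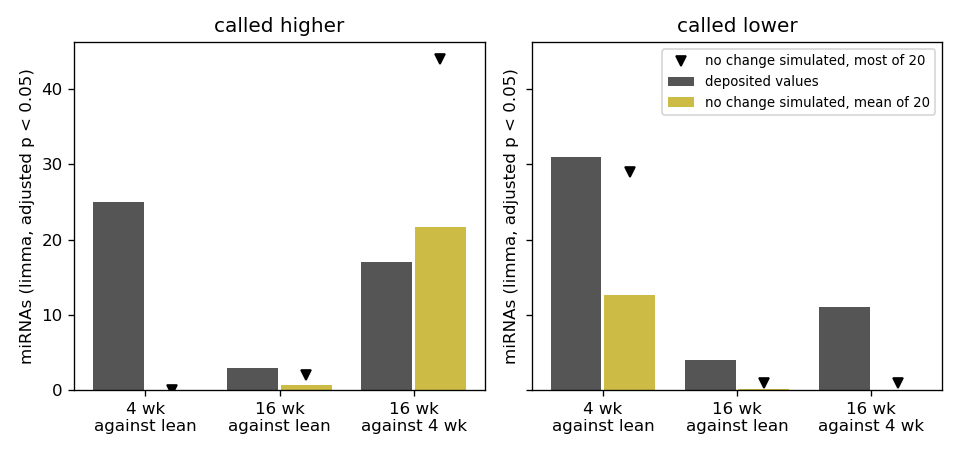
Bars show the number of miRNAs called by limma (adjusted p under 0.05) in the deposited values and the mean over 20 simulated sets with no change, with triangles for the most in any set. At most 29 lower calls arose at 4 weeks and at most 44 higher calls between 16 and 4 weeks with no change, while 0 higher calls arose at 4 weeks.

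Across the 267 miRNAs, the 4-week and 16-week fold changes had a Pearson r of 0.53. miRNAs are not independent replicates, and both comparisons share the lean libraries. Unchanged groups simulated against the same lean libraries gave a mean r of 0.501 (0.390 to 0.606), and splitting the lean libraries between the comparisons gave a mean of 0.279. The covariance was 4.37, against 1.86 simulated. Of the miRNAs called higher, 3 were shared between both comparisons with lean, against a mean of 0 in 100 simulated fits of unchanged groups and 0.281 for independent lists of these sizes. The former leaves out the effects and the latter the shared lean libraries, so the excess is not read as a shared effect. They were miR-146a-5p, miR-24-2-5p and miR-376b-3p, the last with exchanged values and with negative log2 fold changes (-0.50 and -7.50) when these were exchanged back. The 3 shared lower calls, against 0 simulated and 0.464 for independent lists, were miR-329-5p, miR-376c-3p and miR-543-5p, which were at 0 in both HFD groups and whose lean levels lie under the 4-week floor.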

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

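Of the tests in this part, the number of miRNAs at 0 at the 4-week depth and the number still called in the recomputation without miR-101b-3p were set out before their results were seen, and the others only after.

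In 7 miRNAs (miR-155-5p, miR-299a-3p, miR-300-3p, miR-346-5p, miR-376b-3p, miR-434-3p and miR-486a-5p) the lean and 16-week values are not whole reads of their own library. Read as measured in the columns where they stand, the values would be whole reads there, and 0 of 46 were. After exchanging lean and 16-week values with the same replicate number, 44 of 46 became whole reads, which is consistent with an exchange of these values after the CPM were computed. The remaining 2, both of miR-155-5p at 16 weeks, become whole (106 and 118 reads) only if the 2000 and 4000 CPM missing from those columns are added, and how they arose was not tested. The directions as deposited, between lean and 16 weeks and in each comparison with 4 weeks, are therefore not relied on (miR-376b-3p at 4 weeks against lean went from 7.01 to -0.50 with the values exchanged back), and no biological explanation was tested.

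The 4-week libraries were the shallowest. Counting error at low depth is argued against where the count test, which takes depth into account, gave calls in the same direction. These were 9 of 9 tested among the 11 lower at 16 than at 4 weeks, and 17 of 19 among the 23 higher at 4 weeks than in lean and above 0 in both groups. They were also 7 of 7 among the 31 lower at 4 weeks and 5 of 5 among the 17 higher at 16 than at 4 weeks. The count test made 0 calls in simulated groups with no change. These were drawn from its own kind of model with 1 dispersion for all miRNAs, so they do not cover a larger spread. Other effects of low depth were not tested. After thinning to 2335 reads per library, 10 of the 23 were called higher in most of 20 draws. For those that the count test did not test, 24 of the 31 and 12 of the 17, depth may account for the limma calls. Simulated groups with no change gave up to 29 (mean of 12.7) and 44 (21.7) such calls. For the 19 miRNAs above 0 in all lean and at 0 in all 4-week libraries depth and HFD cannot be told apart. For those 19 the test set out beforehand, thinning the lean libraries to the 4-week depths, gave 2 to 8 and so went against depth, but it reuses the reads that chose these miRNAs, and a simulation added afterwards gave 8 to 26. The lower share of miR-101b-3p as a cause of the 23 higher calls was not decided by the test set out beforehand. With CPM recomputed without it, 11 stayed called (median of 3.22 before and 2.21 after). The other 12 lost their call, as their median fell from 2.18 to 1.18 at a median SE of 0.59 and 0.60. The share could thus be part of the cause. In a test added afterwards, 19 of the 23 kept a log2 fold change above 0 by more than 2 SE. The 23 were chosen as higher in the same data, so the share as the whole cause is not excluded. Moreover miR-376b-3p, which is among the 19 and the 11, has exchanged values. A biological difference between the diets stays open.

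Of 28 miRNA names abundant in liver or blood, 24 had a mean under 100 CPM, among them miR-122-5p, let-7a-5p and miR-22-3p. Loss of reads that match several hairpins of the same name is argued against for these names, which were chosen after the values were seen. Of the 21 names with a single hairpin, 18 were also under 100 CPM. Hairpins were counted by name, so reads shared between related names, as in the let-7 family, are not covered, and their loss stays open. Removal of sequences shared with the bovine serum of the medium could give such a pattern, but bovine sequences were not used here, so the 24 names do not decide it. A level of 0 in this table is thus not read as absence from the exosomes, and no biological explanation was tested.

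Chance in the grouping of the libraries is argued against for the number of called miRNAs in each comparison. For 4 weeks against lean 1 of the 35 splits of the 8 libraries, the real one, gave 56 calls, and the highest other gave 6. For 16 weeks against lean 1 of 35 gave 7, with 4 in the highest other, and for 16 against 4 weeks 1 of 35 gave 28, with 2 in the highest other. These splits do not address depth, which goes with the groups.

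Samples far from the others of their group were looked for in 90 groups (30 measures in 3 groups), and 8 stood out, where chance gives about 1 in 20. Lean replicate 2 had 296 miRNAs detected, against 230 to 234 in the others. Lean replicate 4 was high in 4 miRNAs, with 5726 CPM of miR-322-3p (2089 to 2619 in the others), 28696 CPM of miR-351-5p (5766 to 8947), 818 CPM of miR-503-5p (263 to 292) and 49076 CPM of miR-5121 (7347 to 13506). At 4 weeks, replicate 2 had 3401 CPM of miR-511-3p (10495 to 10721 in the others) and replicate 4 had 2699 CPM of miR-511-5p, of which the others had 1 read each. At 16 weeks, replicate 2 had 2118 CPM of miR-1843b-3p (1283 to 1363).

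In 24 of the named miRNAs limma called a difference between the changes from lean at 16 and at 4 weeks, a test that equals the comparison of 16 with 4 weeks. Their number is not read as that of changed miRNAs, since groups with no change gave a mean of 21.7 higher calls. On the log2 scale the difference was 7.62 for miR-16-1-3p, 7.35 for miR-15a-3p, 7.08 for miR-201-5p, 7.06 for miR-16-2-3p, 6.56 for miR-3058-5p, 6.21 for miR-6964-3p, 6.03 for miR-1960 and 5.64 for miR-106a-5p, all at 0 at 4 weeks, and 6.06 for miR-99a-3p, at 64.1 CPM at 4 weeks. These values are set by the pseudocount and are not read as fold changes, since 8 of the 10 calls over a 4-week group at 0 have a 16-week mean under the 4-week floor of 213 CPM, and miR-16-1-3p stood at least 1.03-fold above it. It was 3.12 for miR-802-3p and 1.32 for miR-101b-3p. It was -5.94 for miR-200a-3p (19.2 CPM at 16 weeks, under the floor of 27.1 CPM), -5.89 for miR-6538, -4.27 for miR-3075-5p, -4.09 for miR-1843b-3p, -3.88 for miR-6931-5p, -2.88 for miR-5099, -2.84 for miR-7242-3p, -2.53 for miR-1843a-3p, -1.60 for miR-501-3p and -1.28 for miR-151-3p. Among the miRNAs with exchanged values it was 9.04 for miR-299a-3p, 7.03 for miR-300-3p and -6.98 for miR-486a-5p, and with the values exchanged back it was 4.60, 2.14 and -2.76, none of them called (limma adjusted p = 0.0918, 0.471 and 0.296). Leaving out 1 library also ended the calls for miR-3058-5p (4-week replicate 2 or 16-week replicate 1, limma adjusted p = 0.0602 and 0.0758), miR-1960 (4-week replicate 2, 0.0604), miR-200a-3p (4-week replicate 2 or 16-week replicate 1 or 4, 0.0614 to 0.1), miR-501-3p (4-week replicate 1 or 16-week replicate 1, 0.0587 and 0.0807), miR-99a-3p (4-week replicate 2 or 3 or any 16-week library, 0.0519 to 0.0873) and miR-300-3p with exchanged values (16-week replicate 1, 0.0743).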

How the results depend on the processing

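The alternatives with the 7 miRNAs with exchanged values left out or exchanged back, a mean of at least 1000 CPM, DESeq2, thinning, and those for the share of miR-101b-3p were chosen after seeing the data, and the rest before. Of the 64 calls of named miRNAs, 27 were kept under all settings that tested them, 48 under each left-out library that tested them, and 16 were ended by 1 library. A setting in which a miRNA was not tested was not counted against its call. On leaving out any lean library, for example, miR-329-5p, miR-376c-3p and miR-543-5p were not tested. Thinning and the recomputation without miR-101b-3p were not among these settings. After thinning, 0 of the 21 lower 4-week calls with no 4-week read were called in most draws. The numbers of called miRNAs were 56 at 4 weeks, 7 at 16 weeks and 28 between them. Over libraries left out they ranged from 40 to 60, 3 to 11 and 21 to 44. At 4 weeks the number was 24 with a mean of at least 1000 CPM (fewer miRNAs tested), and 62 with median-of-ratios scaling (15 higher, 47 lower, against 25 and 31). At 16 weeks it was 14 with a pseudocount of 5 (6 higher, 8 lower), 16 with median-of-ratios scaling (3 and 13), 20 with quantile normalization (8 and 12), 12 without the 5 most abundant (3 and 9), 14 without limma's trend (3 and 11), 28 with array weights (13 and 15), 21 with 2 groups only (8 and 13), 25 with edgeR (13 and 12) and 31 with DESeq2 (7 and 24). The cause was not tested. Thinned to 2335 reads per library, the medians were 19.5, 2 and 11, where thinning both lowers depth and ends the depth gap, and these were not told apart. With the replicate number as a replicate block they were 49, 7 and 24. The numbers do not pair the libraries, since the 12 same-number pairs correlated at -0.0697 to 0.0645 after the group means were removed.

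The number of lists called at 4 weeks was 0, and 1 with no filter, with the 7 miRNAs left out or exchanged back, and 3 with fry. At 16 weeks it was 1, and 3 with no filter or fry, but 0 at 100 CPM, with edgeR, at a mean of 1000 CPM (the latter with fewer members tested) and with an estimated correlation, and 0 to 1 over libraries left out. Between 16 and 4 weeks it was 0, and 1 with edgeR and 4 with fry, which asks another question. The profile distance ranged over libraries left out from 6.35 to 11.2 at 16 weeks against lean and from 6.09 to 16.9 between 16 and 4 weeks, and the share of the 10 most abundant at 4 weeks minus lean from -9.32 to -5.40 percentage points, with fewer samples. The correlation of fold changes (0.53) was 0.279 with the lean libraries split, 0.576 with the values exchanged back and 0.429 at a mean of 1000 CPM.

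Directions reversed, the cause not being tested unless the values were exchanged back. At 4 weeks against lean these were miR-376b-3p (-0.50) and miR-434-3p (-5.56) exchanged back, miR-30b-3p (1.04) and miR-100-5p (1.83) with quantile normalization, and miR-511-3p with median-of-ratios (-0.70), quantile (-0.48), without the 5 most abundant (-0.27), edgeR (-0.52) and DESeq2 (-0.73). At 16 weeks against lean they were miR-376b-3p (-7.50), miR-434-3p (-6.89), miR-155-5p (4.21) and miR-300-3p (-4.89) exchanged back, miR-20a-3p with array weights (0.0212) and miR-3075-5p with edgeR (0.18). Between 16 and 4 weeks they were miR-26a-2-3p (-0.17) and miR-98-3p (-0.0504) with array weights, miR-92a-3p with median-of-ratios (0.0879) and edgeR (0.23), miR-17-3p with median-of-ratios (0.33), quantile (0.93), without the 5 most abundant (0.19), edgeR (0.40) and DESeq2 (0.22), and miR-434-3p exchanged back (-1.34). None of these reversed values was called except that of miR-376b-3p at 16 weeks (limma adjusted p = 0.00547).

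Over libraries left out, log2 fold changes at 4 weeks against lean ranged for miR-26a-2-3p from -2.26 to 1.15, let-7c-5p from -0.46 to 2.98, let-7j from -0.53 to 2.55, miR-30d-5p from -0.46 to 2.81, miR-30b-3p from -3.12 to 0.50, miR-511-3p from -0.34 to 0.50, miR-125b-2-3p from -0.26 to 0.0108, miR-100-5p from -2.82 to 0.31 and miR-434-3p (with exchanged values) from -0.35 to 3.47. At 16 weeks against lean they ranged for miR-101b-3p from -0.10 to 0.0286 (its share from -4.67 to 0.626 percentage points), miR-92a-1-5p from -1.89 to 1.85, miR-20a-3p from -2.66 to 0.71, miR-151-3p from -0.20 to 0.0171 and miR-3075-5p from -0.65 to 0.50. Between 16 and 4 weeks they ranged for miR-26a-2-3p from -1.77 to 1.64, miR-98-3p from -1.39 to 1.88, let-7j from -0.11 to 3.17, miR-92a-3p from -0.58 to 0.0521, miR-17-3p from -0.23 to 0.20 and miR-195a-5p from -0.51 to 3.10.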

Other observations

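Of the tests in this part, that of the summed Dlk1-Dio3 members was set out before its result was seen, and that of the miR-322, miR-503 and miR-351 members only after.

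The Dlk1-Dio3 cluster gave the strongest list result at 16 weeks, and its members can be summed so that single miRNAs near the floor weigh little. The hypothesis was that the 27 detected members outside the 7 miRNAs with exchanged values are lower in exosomes of both HFD groups. Their summed CPM was 6410 ± 751 in lean, 3666 ± 1422 at 4 weeks and 663 ± 282 at 16 weeks (SD, n = 4 each), lower than in lean in both comparisons (2-sided exact permutation test, adjusted p = 0.0286 in each, and p = 0.0286 is the smallest the design allows). This is consistent with the hypothesis, but the sum rests largely on miR-541-5p (3334 ± 191, 1254 ± 1058 and 239 ± 144 CPM). Without it the sum was 3077 ± 884, 2413 ± 1067 and 424 ± 166 CPM, and only the 16-week difference from lean held (exact adjusted p = 0.0429, against 0.371 at 4 weeks). Because the same data led to the list result, it remains a hypothesis about HFD and this imprinted cluster, and a loss of reads at low depth is unlikely behind the 16-week value of 0.0286, since the 16-week libraries hold more reads in total than the lean ones.

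The miR-322, miR-503 and miR-351 hairpins lie together on chromosome X, and 3 of their arms were higher at 4 weeks in both tests. The hypothesis that the sum of their 6 names is higher in both HFD groups was not borne out. The sum was 18700 ± 14542 CPM in lean, 69557 ± 30323 at 4 weeks and 41755 ± 19366 at 16 weeks (SD, n = 4 each). At 4 weeks all libraries lay apart from lean (exact permutation p = 0.0286, the smallest possible), but neither comparison passed after adjustment (adjusted p = 0.0857 at 4 weeks and 0.129 at 16 weeks), and lean replicate 4 was far above the other lean libraries in 3 of these miRNAs. A single comparison at the smallest p cannot pass this adjustment, so the 4-week miss follows from the design. At 16 weeks the exact permutation p was 0.0857 before adjustment.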
